A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

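Gene expression was measured on 18 Affymetrix yeast arrays, hybridized with biotin-labelled RNA from Saccharomyces cerevisiae cultures. Total RNA had been isolated with a FastRNA kit from cells grown aerobically in 1-litre bioreactors at 30 °C and pH 5.0, with 40 g/L glucose at the start. Samples were taken at 15 to 20 g/L (high) or 5 g/L (low) glucose, and per the labels at steady state. All strains were, per the labels, snf1 deletion mutants that carried a plasmid. HA-Snf1 was the reference, HA-Alpha1 encoded the catalytic domain of the mammalian AMPK Alpha1 subunit joined to the regulatory domain of Snf1, and HA-T210A encoded Snf1 with its activation site, Thr210, changed to Ala. The labels call the 3 arrays of each of the 6 groups biological replicates and say nothing beyond that about how the cultures were related.

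The deposited values are log2 signals per probe set. RMA and the affy package are credited to the submitters' processing notes, and no further scaling was applied here. The table held 5716 probe sets with values from 2.25 to 14.3, and the array medians ran from 6.80 to 7.05. The arrays did not share one distribution over these probe sets. Of the probe sets, 5498 named 1 gene and 218 named none, and 12 symbols were updated to current ones. For 47 genes with several probe sets the one with the highest mean stood for the gene, which left 5449 genes. No 2 arrays were identical, and the smallest SD of the difference between 2 arrays was 0.145. All columns of the table were matched to a group. The number of arrays limits the precision of every value.

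Differences were tested with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 6 groups over all 18 arrays, with 12 residual degrees of freedom and a prior of 1.18. The moderated test of limma gave p-values for 12 comparisons, which comprised the 9 contrasts of 2 groups and 3 differences between the glucose responses of a pair of strains. Benjamini-Hochberg adjustment was made over the 5449 genes of each comparison, and a gene was called at an adjusted p under 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over 35 lists that were fixed in advance and had at least 5 measured members. Each list was also tested with camera at an estimated correlation and with fry. Differences are given as log2 ± SE from the model, with n = 3 arrays per group throughout, and group means are given with their SD. The SE rests on the variance of a gene pooled over all 6 groups. It therefore understates the spread of a gene that varied more in 1 group, as many did in Alpha1 at low glucose. A group mean under 3.25, which is 1 log2 unit above the average lowest signal of the arrays, is described as close to the floor. Means just above this line carry no such remark, although folds taken from them are uncertain too. Examples are HXT2 in T210A at low glucose (3.30) and INO1 in T210A at high glucose (3.31).

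The comparisons, the lists, the rule for the genes to be named and most alternatives were chosen before the data were examined. The rule took, for each contrast of 2 groups, the 8 largest called differences in each direction among genes whose 3 arrays of one group all lay on one side of the 3 of the other (6 for Alpha1 against T210A, 5 for the response differences, where no such condition was set), 12 anchor genes and up to 4 members of each list called. By chance 10% of genes show such a separation in a contrast of 3 with 3 arrays. The probe set for SNF1 may read plasmid transcripts as well as any chromosomal one, so its signal was not taken as a test of the deletion.

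The procedure was tested on simulated data with 200 changed genes among 5449 in each of 5 simulations. At a difference of 1 on the log2 scale it recovered 92.8% of the changed genes for Alpha1 against Snf1 at high glucose and 76.4% for the difference between the T210A and Snf1 responses, and at 0.5 it recovered 52.5% and 28.1%. The mean number of false calls was between 6.2 and 12.6 per comparison. Of 60 simulated lists of 30 members shifted by 0.5, all 60 were found, and 0 of 1800 lists without a shift were called. Simulated genes varied independently of each other, each with the same SD in all groups. These rates therefore do not cover lists of correlated genes or groups that differ in spread.

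Alternatives comprised an intensity trend with a robust prior, a fit of the compared groups alone, the replicate number as a block, quantile normalization, median centring, filters on dim genes, the mean of all probe sets, all probe sets, a minimum fold of 2 and the omission of each array in turn. Omission of the chromosome VIII genes and array weights were added after the data had been seen. Whether replicate numbers paired the arrays was checked by correlating, across genes, the deviations of arrays with the same number. The lowest of the 3 correlations was above 0.1 in 8 of the 15 pairs of groups, for example 0.38 between Snf1 and T210A at high glucose, and it was -0.24 between Alpha1 and T210A at high glucose. The labels do not describe a pairing, so the block served as an alternative.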

Results

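The transcriptomes of 3 yeast strains were compared at 2 residual glucose levels. Each strain lacked the chromosomal SNF1 gene and carried 1 plasmid. Snf1 is the yeast kinase, related to mammalian AMP-activated protein kinase (AMPK), that is needed for expression of many glucose-repressed genes. The reference strain expressed HA-Snf1, the Alpha1 strain a fusion of the mammalian Alpha1 catalytic domain with the Snf1 regulatory domain, and the T210A strain a Snf1 whose activation site was replaced. Samples were taken at 15 to 20 g/L residual glucose (high) and at 5 g/L (low), with 3 arrays in each of the 6 groups. The labels call the samples steady state although both levels lie below the starting 40 g/L, so low against high glucose is read here as a difference between 2 levels, whether or not they were successive in a culture. The series title asks how far AMPK and Snf1 are interchangeable, so the fusion was set against a strain with Snf1 and a strain with the replaced site.

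Arrays of 1 group correlated across genes at 0.992 to 0.998, except those of Alpha1 at low glucose, which correlated at 0.978 to 0.984. The median SD of a gene within a group was between 0.104 and 0.125 in 5 groups and 0.221 in Alpha1 at low glucose. In that group the deviation of replicate 3 from the group mean correlated with the Snf1 glucose response across genes (r = 0.64), and those of replicates 1 and 2 did so at -0.28 and -0.26. Genes are not independent replicates, so these correlations carry no p-value.

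The first comparison is between low and high glucose in the reference strain. At low glucose HXK1, which encodes a hexokinase, was 156-fold higher than at high glucose (7.28 ± 0.27, adjusted p = 2.66e-11), and the maltase gene MAL32 was 130-fold higher (7.02 ± 0.32). SUC2 (YIL162W), which encodes invertase, rose 52.0-fold, from a mean of 6.36 (SD 0.24) to 12.06 (SD 0.15). The lactate permease gene JEN1 rose 84.5-fold (6.40 ± 0.38) and INO1, which encodes inositol-3-phosphate synthase, 93.3-fold (6.54 ± 0.24). The anchor genes ADH2 and FBP1 had means close to the floor at both levels in this strain. From high to low glucose these were 2.77 (SD 0.07) and 2.79 (SD 0.11) for ADH2, and 2.32 and 3.13 (SD 0.36) for FBP1. The low-affinity glucose transporter gene HXT1 was 29.6-fold lower (-4.89 ± 0.21), and NSR1, which encodes a nucleolar protein of ribosome synthesis, was 28.8-fold lower (-4.85 ± 0.11).

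Respiratory genes rose as a group in the reference strain. All 39 measured members of the respiratory chain and ATP synthase list were higher, also when adjusted over the list alone, with a median difference of 1.29 (adjusted p = 7.00e-14, and adjusted p = 0.232 with an estimated correlation). All 65 mitochondrial ribosome genes were higher, also when adjusted over the list alone (median 1.04, adjusted p = 1.41e-14, and adjusted p = 0.332 with an estimated correlation). Of 22 glycogen and trehalose genes 21 rose and 1 fell, with the same counts when adjusted over the list alone. Their median was 3.46, and PGM2, encoding a phosphoglucomutase, rose 99.8-fold (adjusted p = 4.63e-10 for the list, and adjusted p = 0.321 with an estimated correlation). The 88 ribosome biogenesis genes all fell, also when adjusted over the list alone, with a median of -3.32 (adjusted p = 1.02e-35, and adjusted p = 0.164 with an estimated correlation). Of 128 genes in the cytosolic ribosomal protein list, which was matched by symbol and so also holds the RNase P gene RPP1, 121 fell (123 when adjusted over the list alone), with a median of -0.86 (adjusted p = 1.01e-16, and adjusted p = 0.422 with an estimated correlation). In all, 3669 of 5449 genes were called, 1889 higher and 1780 lower, and 74.2% of genes had no overlap between the groups where chance gives 10%.

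In the Alpha1 strain INO1, HXK1 and PGM2 were also far higher at low glucose, as were SUC2 and JEN1 by smaller folds than in Snf1. INO1 rose 324-fold (8.34 ± 0.24, adjusted p = 9.60e-12), HXK1 179-fold (7.48 ± 0.27) and PGM2 84.7-fold (6.40 ± 0.18). SUC2 rose 12-fold (3.59 ± 0.37), from 6.35 (SD 0.20) to 9.94 (SD 1.02). JEN1 rose 7.08-fold (2.82 ± 0.38) from a mean of 3.09 at high glucose, which is close to the floor, and 4.48-fold (2.16) without Alpha1_low replicate 3. The high-affinity glucose transporter gene HXT2 had means of 5.73 (SD 0.21) at high and 5.75 (SD 0.88) at low glucose, which did not pass the test (adjusted p = 0.997). HXT1 was 43.3-fold lower (-5.44 ± 0.21).

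All 39 respiratory chain and ATP synthase genes also rose in Alpha1, likewise when adjusted over the list alone (median 1.03, adjusted p = 3.69e-13, and adjusted p = 0.275 with an estimated correlation). Of 21 gluconeogenesis and glyoxylate cycle genes 13 rose and 2 fell, with the same counts when adjusted over the list alone (median 0.65, adjusted p = 0.0087, and adjusted p = 0.432 with an estimated correlation). Among them ICL1, encoding isocitrate lyase, rose 1.57-fold (0.65 ± 0.15). The 88 ribosome biogenesis genes all fell, also when adjusted over the list alone, with a median of -2.01 (adjusted p = 1.82e-34, and adjusted p = 0.185 with an estimated correlation). Of 33 proteasome genes 17 rose and none fell (16 and 0 when adjusted over the list alone), with a median of 0.27 (adjusted p = 0.0110, and adjusted p = 0.299 with an estimated correlation). The count was 3461 genes, 1868 higher and 1593 lower, and 60.2% of genes had no overlap against 10% by chance.

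In T210A, the strain with the replaced activation site, stress and respiratory genes were higher at low glucose and SUC2 did not pass the test. The membrane heat shock gene HSP30 rose 202-fold (7.66 ± 0.31, adjusted p = 2.24e-10), HXK1 65.3-fold (6.03 ± 0.27), INO1 54.4-fold (5.77 ± 0.24) and the lactate dehydrogenase gene CYB2 58.5-fold (5.87 ± 0.10). SUC2 had means of 6.15 (SD 0.29) and 6.78 (SD 0.30), a difference of 0.63 ± 0.37 (adjusted p = 0.142). HXT2, which was 5.37-fold higher at low glucose in the reference strain, was 7.15-fold lower at low glucose in T210A (-2.84 ± 0.31). PCK1, encoding phosphoenolpyruvate carboxykinase, rose 3.27-fold (1.71 ± 0.16), and the general amino acid permease gene GAP1 was 12.3-fold lower (-3.62 ± 0.22).

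All 34 general stress response genes rose in T210A, also when adjusted over the list alone (median 3.39, adjusted p = 5.49e-14, and adjusted p = 0.330 with an estimated correlation), as did all 39 respiratory chain and ATP synthase genes (also 39 when adjusted over the list alone; median 1.23, adjusted p = 3.40e-13, and adjusted p = 0.220 with an estimated correlation). Of 65 mitochondrial ribosome genes 45 rose and 20 did not pass, with the same counts when adjusted over the list alone (median 0.39, adjusted p = 4.39e-05, and adjusted p = 0.567 with an estimated correlation). Of 33 proteasome genes 24 fell and 1 rose, with the same counts when adjusted over the list alone (median -0.35, adjusted p = 1.61e-04, and adjusted p = 0.220 with an estimated correlation), and RPT4, a proteasome ATPase gene, was 1.76-fold lower. The 88 ribosome biogenesis genes all fell, also when adjusted over the list alone, with a median of -1.70 (adjusted p = 5.33e-27, and adjusted p = 0.220 with an estimated correlation). The count was 3841 genes, 2055 higher and 1786 lower, and 76.7% of genes had no overlap against 10% by chance. The SUC2 difference passed in a fit of the compared groups alone (adjusted p = 0.0427) and with array weights (adjusted p = 0.0105). Over all alternatives its adjusted p ran from 0.0105 to 0.347.

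**Figure D1:**
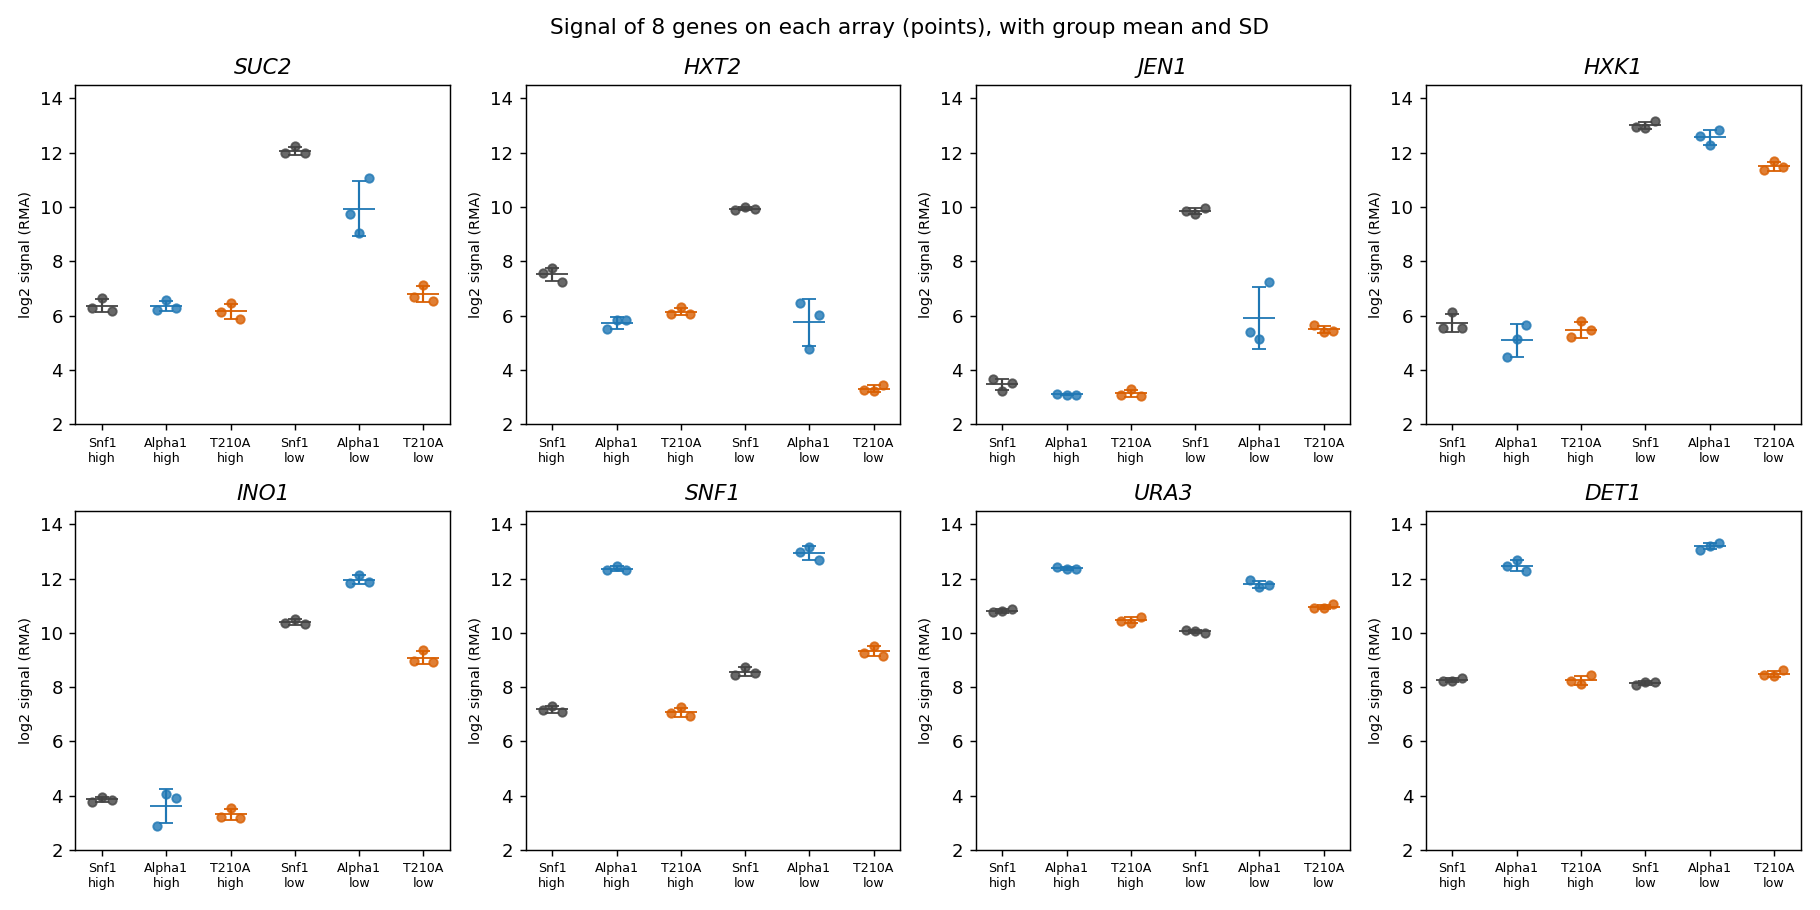
Log2 RMA signal of 8 genes (vertical axes) on each of the 18 arrays, grouped by strain and glucose level (horizontal axes), with points for arrays, long lines for group means and bars for the SD (n = 3). At low glucose SUC2 has means of 12.06 in Snf1, 9.94 in Alpha1 and 6.78 in T210A, while SNF1, URA3 and DET1 lie highest in Alpha1 at both glucose levels.

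At high glucose Alpha1 was first compared with Snf1. The largest increases in Alpha1 were of SNF1 (YDR477W), 36.5-fold above the reference (5.19 ± 0.13, adjusted p = 1.36e-11; means 12.36, SD 0.09, and 7.17, SD 0.13), and DET1 (YDR051C), 18.6-fold above it (4.22 ± 0.11). URA3 (YEL021W), a pyrimidine synthesis gene widely used as a plasmid marker, was 2.97-fold higher (1.57 ± 0.07, adjusted p = 1.74e-08). The ammonium permease gene MEP2 was 2.51-fold higher (1.33 ± 0.19) and the Hsp70 gene SSA1 1.84-fold higher (0.88 ± 0.11). Lower genes included the cell wall mannoprotein gene CWP1, 4.01-fold (-2.00 ± 0.21), TMA10, 3.64-fold (-1.86 ± 0.21), PRM5, 3.09-fold (-1.63 ± 0.24), and HXT2, 3.45-fold (-1.79 ± 0.31, adjusted p = 0.0113).

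Of 26 nitrogen catabolite-repressed genes 4 were higher and none lower in Alpha1 at high glucose (7 and 1 when adjusted over the list alone), with a median of 0.21 (adjusted p = 2.87e-08, and adjusted p = 0.454 with an estimated correlation). Of 29 unfolded protein and heat shock genes 2 were higher (7 when adjusted over the list alone), with a median of 0.19 (adjusted p = 6.28e-09, and adjusted p = 0.454 with an estimated correlation). The mitochondrial ribosome list shifted by a median of -0.13 although none of its 65 genes passed, also when adjusted over the list alone (adjusted p = 2.48e-08, and adjusted p = 0.909 with an estimated correlation). In all 50 genes were called, 17 higher and 33 lower, 408 had an unadjusted p under 0.05, and 14% of genes had no overlap against 10% by chance. The count fell to 19 without Snf1_high replicate 1, 25 without Alpha1_high replicate 2 and 30 without Alpha1_high replicate 3, and it was 85 with arrays centred on their medians and 396 with array weights. The HXT2 call ended without Alpha1_high replicate 1 (adjusted p = 0.0561), Snf1_high replicate 1 (0.0605) or Snf1_high replicate 2 (0.0554), within a range of 3.58e-06 to 0.0605 over all alternatives.

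The comparison of T210A with Snf1 at high glucose was dominated by genes of 1 chromosome. The median difference over the 261 measured genes of chromosome VIII was 0.74, and 95% of them were positive. The 8 genes with the largest increases included FSH1 (2.55-fold, 1.35 ± 0.14, adjusted p = 4.92e-05), MIP6 (2.49-fold, 1.32 ± 0.07) and SPO12 (2.34-fold, 1.23 ± 0.11), which lie on chromosome VIII. Of its genes 181 were higher and none lower, while among the 5188 genes elsewhere 13 were higher and 34 lower. DDR48, a stress gene on chromosome XIII, was 1.83-fold higher (0.87 ± 0.08). The lower genes included HXT2 (2.59-fold, -1.38 ± 0.31, adjusted p = 0.0170), the dicarboxylic amino acid permease gene DIP5 (2.02-fold, -1.02 ± 0.14) and the sulfate permease gene SUL1 (1.78-fold, -0.83 ± 0.08).

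Of 34 general stress response genes 5 were higher in T210A at high glucose (7 when adjusted over the list alone), with a median of 0.09 (adjusted p = 0.0019, and adjusted p = 0.996 with an estimated correlation). Among these the aldose reductase gene GRE3 (2.14-fold) and SOD2, encoding mitochondrial superoxide dismutase (1.99-fold), lie on chromosome VIII. The 6 ribosome biogenesis genes that were higher of 88 (also 6 when adjusted over the list alone; median 0.08, adjusted p = 1.38e-05, and adjusted p = 0.996 with an estimated correlation), among them the helicase gene DBP8 (2.17-fold) and RPF1 (2.07-fold), all lie on chromosome VIII. In all 228 genes were called, 194 higher and 34 lower, and 18.8% of genes had no overlap against 10% by chance. With the fit and adjustment repeated without chromosome VIII genes 18 were called, 7 higher and 11 lower, and with array weights 572 were called, both alternatives being chosen after the data had been seen. The HXT2 call ended, at an unchanged difference of -1.38, when these genes were left out (adjusted p = 0.111), and it ended without T210A_high replicate 1 (0.0705), T210A_high replicate 3 (0.0702), Snf1_high replicate 1 (0.0680) or Snf1_high replicate 2 (0.0772), within a range of 5.43e-06 to 0.111 over all alternatives.

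**Figure D2:**
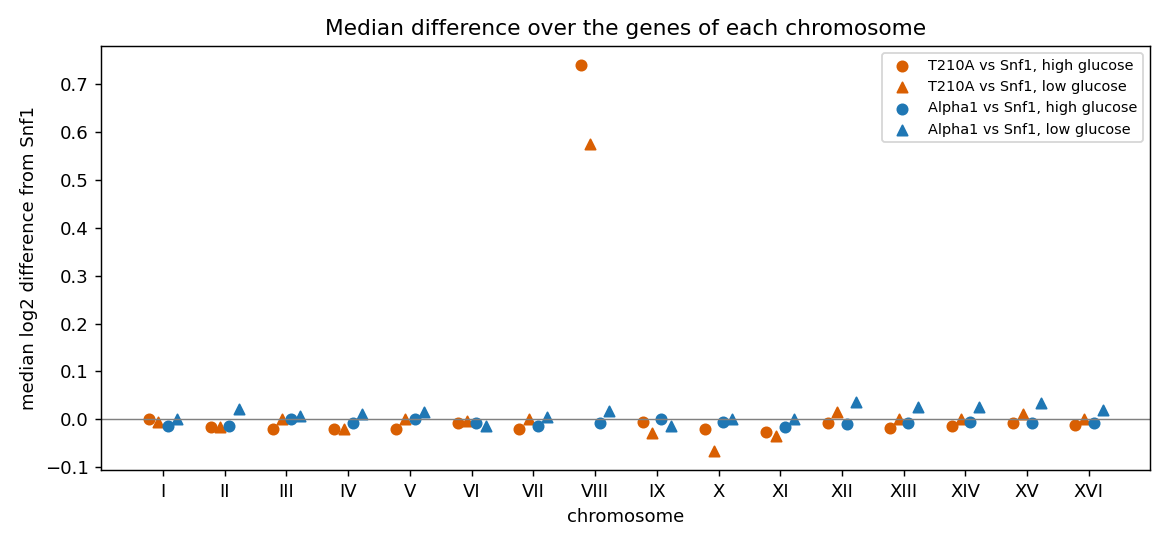
Median log2 difference from Snf1 over the measured genes of each chromosome (vertical axis) for the 16 nuclear chromosomes (horizontal axis), with circles for high and triangles for low glucose. In T210A the chromosome VIII medians are 0.74 and 0.57, and in Alpha1 they are -0.01 and 0.02.

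Alpha1 and T210A were also compared directly at high glucose. SNF1 was 39.0-fold higher in Alpha1 (5.29 ± 0.13, adjusted p = 1.17e-11), DET1 18.7-fold (4.23 ± 0.11) and URA3 3.77-fold (1.91 ± 0.07). The copper transporter gene CTR3 was 2.18-fold higher (1.12 ± 0.19) and MEP2 2.13-fold (1.09 ± 0.19). CWP1 was 3.98-fold lower (-1.99 ± 0.21), and RTC3 (-2.09 ± 0.25), CRG1 (-2.07 ± 0.29) and the cell integrity kinase gene SLT2 (-1.59 ± 0.28), all on chromosome VIII, were 4.25-fold, 4.2-fold and 3.02-fold lower. The median over chromosome VIII was -0.74.

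Of 34 general stress response genes 6 were lower in Alpha1 than in T210A at high glucose (9 when adjusted over the list alone), among them HSP12 (1.94-fold) and, on chromosome VIII, GRE3 (2.30-fold) and SOD2 (2.02-fold), with a median of -0.25 (adjusted p = 1.40e-04, and adjusted p = 0.956 with an estimated correlation). Of 37 cell wall and cell integrity genes 5 were lower and none higher (8 and 1 when adjusted over the list alone), among them SED1 (2.49-fold), with a median of -0.20 (adjusted p = 0.0015, and adjusted p = 0.956 with an estimated correlation). Of 21 genes for phospholipid synthesis under inositol control 3 were higher and 2 lower (7 and 3 when adjusted over the list alone), with a median of 0.22 (adjusted p = 0.0176, and adjusted p = 0.956 with an estimated correlation). The methyltransferase gene CHO2 was 1.65-fold higher, and INM1, on chromosome VIII, was 2.15-fold lower. In all 344 genes were called, 82 higher and 262 lower, and 25% of genes had no overlap against 10% by chance. On chromosome VIII 186 genes were lower and none higher. Quantile normalization gave 150 higher and 287 lower genes, and a fit and adjustment without the chromosome VIII genes gave 41 and 39. The count was 543 with the replicate block (200 higher, 343 lower) and 1241 with array weights.

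At low glucose the Alpha1 strain had lower signals than Snf1 for HXT2, HXT17, JEN1, FLO11 and SUC2. The hexose transporter genes HXT2 and HXT17 were 18.3-fold lower (-4.20 ± 0.31, adjusted p = 4.48e-07) and 45.4-fold lower (-5.50 ± 0.20), the latter with an Alpha1 mean close to the floor and 12.2-fold lower (-3.61) with the mean of its probe sets. JEN1 was 15.5-fold lower (-3.95 ± 0.38), and 24.5-fold lower (-4.61) without Alpha1_low replicate 3. The flocculin gene FLO11 was 7.43-fold lower (-2.89 ± 0.26) and SUC2 4.34-fold (-2.12 ± 0.37, adjusted p = 6.93e-04). Higher signals were seen for DET1 (33.1-fold, 5.05 ± 0.11), the aryl-alcohol dehydrogenase gene AAD6 (25.7-fold, 4.68 ± 0.40) and SNF1 (20.7-fold, 4.37 ± 0.13). INO1 was 2.93-fold higher (1.55 ± 0.24), and ACC1, encoding acetyl-CoA carboxylase, a known substrate of Snf1, was 1.33-fold higher (0.41 ± 0.06).

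Of 88 ribosome biogenesis genes 86 were higher in Alpha1 than in Snf1 at low glucose (87 when adjusted over the list alone), with a median of 1.29 (adjusted p = 1.89e-48, and adjusted p = 0.0567 with an estimated correlation). NOG2, a GTPase gene of large-subunit assembly, was 3.79-fold higher and UTP18, a gene of the small-subunit processome, 3.78-fold. Of 21 gluconeogenesis and glyoxylate cycle genes 14 were lower and 1 higher, with the same counts when adjusted over the list alone (median -0.91, adjusted p = 2.91e-08, and adjusted p = 0.241 with an estimated correlation). They included CAT8, the activator of these genes (3.32-fold, -1.73 ± 0.17), ICL1 (3.13-fold, -1.64 ± 0.15) and IDP2 (3.77-fold, -1.92 ± 0.15). Of 16 TCA cycle genes 13 were lower and none higher, also when adjusted over the list alone (median -0.66, adjusted p = 5.65e-08, and adjusted p = 0.241 with an estimated correlation). Of 39 respiratory chain and ATP synthase genes 25 were lower (30 when adjusted over the list alone), with a median of -0.37 (adjusted p = 5.66e-11, and adjusted p = 0.241 with an estimated correlation). Of 29 unfolded protein and heat shock genes 10 were higher, also when adjusted over the list alone (median 0.38, adjusted p = 0.0010, and adjusted p = 0.474 with an estimated correlation). In this group of arrays the SD within the group was largest, as given above, and the SDs of SUC2 and JEN1 in Alpha1 were 1.02 and 1.15.

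In all 1632 genes differed between Alpha1 and Snf1 at low glucose, 927 higher and 705 lower, and 33.7% of genes had no overlap against 10% by chance. Without Alpha1_low replicate 3 the count was 1899. In a fit of the compared groups alone it was 603, and the SUC2 call ended (adjusted p = 0.0726, the highest of a range from 3.16e-06 over all alternatives).

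At low glucose T210A differed from Snf1 at single genes such as SUC2 and HXT2 and across chromosome VIII. HXT2 was 99.7-fold lower than in Snf1 (-6.64 ± 0.31, adjusted p = 1.39e-09), the kinase gene MRK1 58.9-fold (-5.88 ± 0.38), SUC2 38.9-fold (-5.28 ± 0.37, adjusted p = 5.91e-08) and JEN1 20.8-fold (-4.38 ± 0.38). The glycogen synthase gene GSY1 was 14.1-fold lower (-3.82 ± 0.13) and the proline permease gene PUT4 21.2-fold lower (-4.41 ± 0.25). The amino acid permease gene BAP3 was 39.2-fold higher (5.29 ± 0.29), EFM6 17.0-fold (4.09 ± 0.18), and INM1, on chromosome VIII, 25.1-fold (4.65 ± 0.17). The median difference over chromosome VIII genes was 0.57, and whether it bears on genes of other chromosomes was not tested. SNF1 itself was 1.67-fold higher (0.74 ± 0.13), HXK1 2.83-fold lower (-1.50 ± 0.27) and INO1 2.51-fold lower (-1.33 ± 0.24). PCK1, with means of 6.05 (SD 0.18) in T210A and 5.71 (SD 0.15) in Snf1, and the acetyl-CoA synthetase gene ACS1, with means of 7.62 (SD 0.24) and 7.35 (SD 0.19), did not pass (adjusted p = 0.0867 and 0.20).

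Of 88 ribosome biogenesis genes 85 were higher in T210A at low glucose, also when adjusted over the list alone (median 1.64, adjusted p = 2.43e-30, and adjusted p = 0.137 with an estimated correlation). Of 65 mitochondrial ribosome genes 60 were lower (61 when adjusted over the list alone), with a median of -0.84 (adjusted p = 4.29e-17, and adjusted p = 0.524 with an estimated correlation), and MRPL39 was 2.39-fold lower. Of 33 proteasome genes 26 were lower and 1 higher, with the same counts when adjusted over the list alone (median -0.57, adjusted p = 2.02e-08, and adjusted p = 0.0578 with an estimated correlation), and the ATPase gene RPT2 was 1.88-fold lower. Of 63 amino acid biosynthesis genes 45 were higher and 8 lower, with the same counts when adjusted over the list alone (median 0.79, adjusted p = 9.29e-07, and adjusted p = 0.766 with an estimated correlation). CPA1, a carbamoyl phosphate synthetase gene, was 6.59-fold higher, the aspartate kinase gene HOM3 5.12-fold and HIS3 4.39-fold. Of 16 alternative sugar use genes 11 were lower, also when adjusted over the list alone (median -1.03, adjusted p = 8.01e-04, and adjusted p = 0.524 with an estimated correlation). In all 3066 genes were called, 1621 higher and 1445 lower, and 67.4% of genes had no overlap against 10% by chance. On chromosome VIII 172 were higher and 13 lower.

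**Figure D3:**
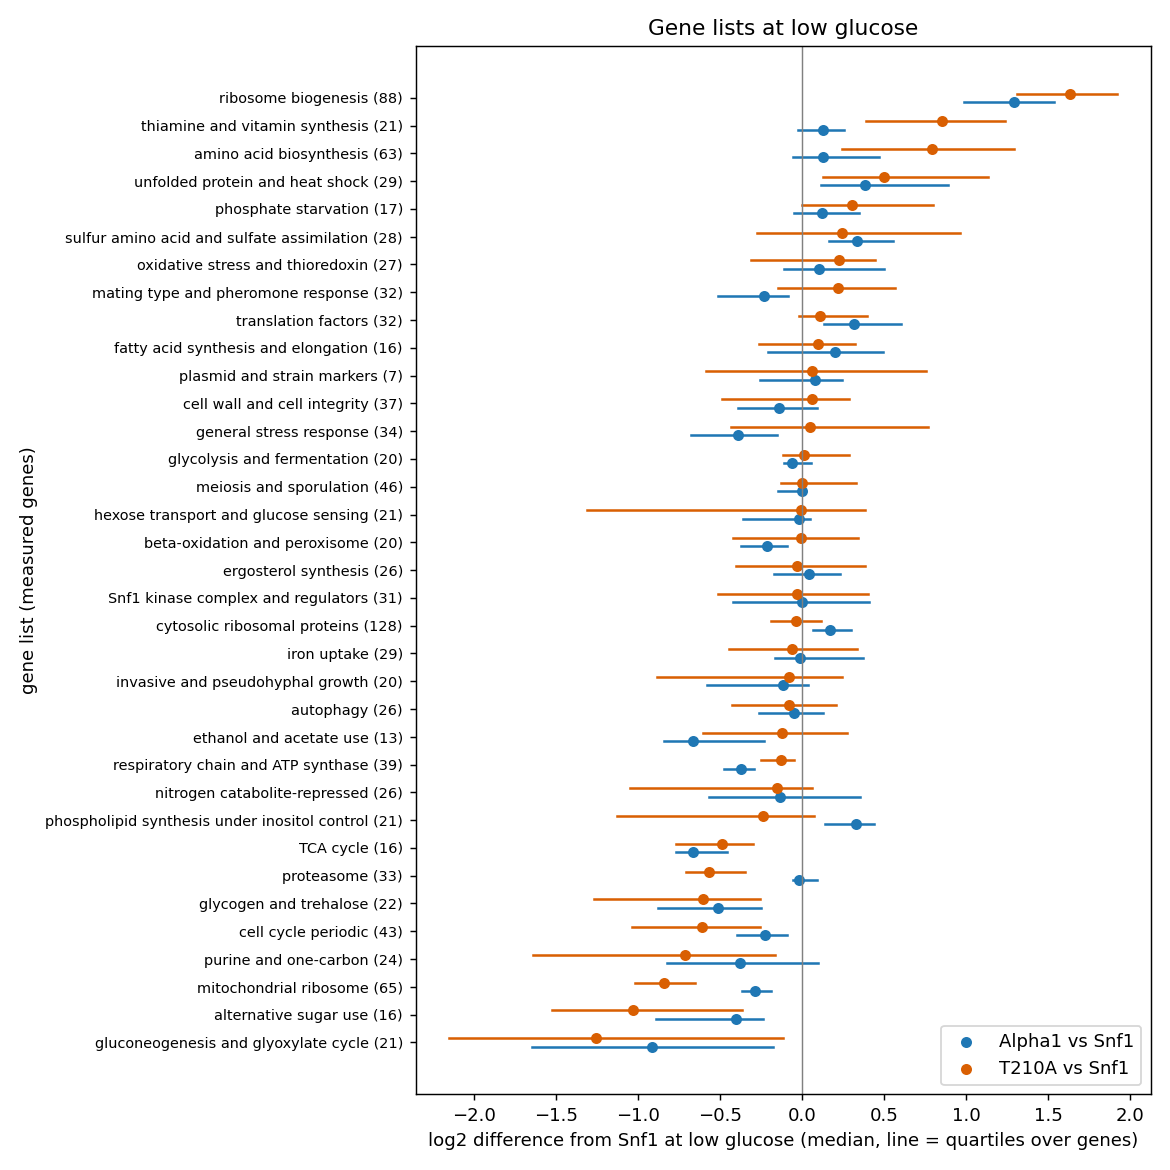
Median log2 difference from Snf1 at low glucose (horizontal axis) for each of the 35 gene lists (vertical axis, measured genes in brackets), in blue for Alpha1 and in orange for T210A, with lines from the lower to the upper quartile over the genes. Ribosome biogenesis has medians of 1.29 and 1.64, and the proteasome list has a median of -0.57 in T210A.

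Between Alpha1 and T210A at low glucose, SUC2, HXT2 and several other genes were higher in Alpha1, and PCK1 and ICL1 were lower. SUC2 was 8.97-fold higher in Alpha1 (3.16 ± 0.37, adjusted p = 1.59e-05), HXT2 5.43-fold (2.44 ± 0.31), MRK1 11.8-fold (3.56 ± 0.38; 7.68-fold without Alpha1_low replicate 3 and 18.8-fold with array weights), INO1 7.36-fold (2.88 ± 0.24) and HXK1 2.09-fold (1.07 ± 0.27). ACC1 was 1.4-fold higher (0.48 ± 0.06). JEN1, with means of 5.91 (SD 1.15) in Alpha1 and 5.49 (SD 0.13) in T210A, did not pass (adjusted p = 0.406). PCK1 was 1.61-fold lower in Alpha1 (-0.69 ± 0.16, adjusted p = 0.0039) and ICL1 1.31-fold lower (-0.39 ± 0.15, adjusted p = 0.0493). The vitamin B6 genes SNO1 and SNZ1 were 12.7-fold (-3.67 ± 0.18) and 7.10-fold (-2.83 ± 0.16) lower in Alpha1, HSP30 6.30-fold (-2.66 ± 0.31), and BAP3 60.9-fold (-5.93 ± 0.29) with an Alpha1 mean close to the floor.

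Of 33 proteasome genes 25 were higher and 1 lower in Alpha1 than in T210A at low glucose (28 and 1 when adjusted over the list alone), with a median of 0.58 (adjusted p = 1.20e-11), and this call held with an estimated correlation (adjusted p = 0.0147). Of 65 mitochondrial ribosome genes 55 were higher (58 when adjusted over the list alone), with a median of 0.55 (adjusted p = 3.13e-13, and adjusted p = 0.656 with an estimated correlation). Of 63 amino acid biosynthesis genes 40 were lower and 9 higher (42 and 9 when adjusted over the list alone), among them CPA1 (4.06-fold lower) and HIS3 (3.72-fold lower), with a median of -0.63 (adjusted p = 1.04e-07, and adjusted p = 0.656 with an estimated correlation). Of 32 mating type and pheromone response genes 19 were lower (20 when adjusted over the list alone), with a median of -0.48 (adjusted p = 1.02e-05, and adjusted p = 0.404 with an estimated correlation). In all 2263 genes were called, 1132 higher and 1131 lower, and 43.5% of genes had no overlap against 10% by chance. The median over chromosome VIII was -0.61, with 178 genes lower and 7 higher. The arrays of Alpha1 at low glucose spread most, and a fit of the compared groups alone called 1244 genes and ended the PCK1 call (adjusted p = 0.0730, the highest of a range from 6.30e-04). The ICL1 call ended there (0.220), with an intensity trend (0.0508), with array weights (0.359), without chromosome VIII genes (0.0511) and without Alpha1_low replicate 1 (0.213) or 3 (0.0646) or T210A_low replicate 2 (0.197) or 3 (0.10), in a range from 0.0036 to 0.359.

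The glucose responses themselves were compared between strains, which tests whether the change from high to low glucose differed. Across genes the Snf1 response correlated with that of Alpha1 at 0.94 and with that of T210A at 0.81, and those of Alpha1 and T210A at 0.88. In all 3 strains 1375 genes rose and 1199 fell. The SUC2 response was 4.32-fold smaller in Alpha1 than in Snf1 (-2.11 ± 0.52, adjusted p = 0.0153) and the JEN1 response, with an Alpha1 mean close to the floor at high glucose, differed by -3.58 ± 0.54, and by -4.24 without Alpha1_low replicate 3. ICL1 (-1.51 ± 0.21) and HXT2 (-2.41 ± 0.43) also responded less, while INO1 (1.80 ± 0.33) and ACC1 (0.44 ± 0.08) responded more.

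Of 88 ribosome biogenesis genes 82 had a weaker fall in Alpha1 than in Snf1, seen as a positive difference (84 when adjusted over the list alone), with a median of 1.29 (adjusted p = 1.67e-55), and this call held with an estimated correlation (adjusted p = 0.0337). Of 21 gluconeogenesis and glyoxylate cycle genes 11 had a negative difference (12 when adjusted over the list alone), with a median of -1.03 (adjusted p = 3.49e-08, and adjusted p = 0.395 with an estimated correlation). Of 16 TCA cycle genes 7 had one (10 when adjusted over the list alone), with a median of -0.50 (adjusted p = 1.86e-06, and adjusted p = 0.395 with an estimated correlation). The responses of 746 genes differed, 508 with a positive and 238 with a negative difference, and 512 and 421 did so after quantile normalization. The count was 1158 without Alpha1_low replicate 1 and 491 in a fit of the compared groups alone, where the SUC2 call ended (adjusted p = 0.0560, the highest of a range from 9.47e-05 over all alternatives).

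T210A differed from Snf1 in its glucose response at 2153 genes, 1155 with a positive and 998 with a negative difference. SUC2 (-5.07 ± 0.52, adjusted p = 6.76e-06), JEN1 (-4.05 ± 0.54, with a T210A mean close to the floor at high glucose) and the phosphatase regulator gene REG2 (-4.04 ± 0.24) had smaller responses in T210A. The HXT2 responses (-5.26 ± 0.43) had opposite directions, up in Snf1 and down in T210A. Positive differences included BAP3 (5.94 ± 0.41) and EFM6 (4.12 ± 0.25). Array weights gave 3252 genes. Of 33 proteasome genes 25 had a negative and 1 a positive difference (28 and 1 when adjusted over the list alone), with a median of -0.65 (adjusted p = 2.20e-11), and this call held with an estimated correlation (adjusted p = 0.0173). Of 88 ribosome biogenesis genes 83 had a positive difference (84 when adjusted over the list alone), with a median of 1.52 (adjusted p = 2.29e-33, and adjusted p = 0.102 with an estimated correlation). Of 63 amino acid biosynthesis genes 40 had a positive and 8 a negative difference (41 and 8 when adjusted over the list alone), with a median of 0.81 (adjusted p = 3.18e-07, and adjusted p = 0.584 with an estimated correlation).

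Alpha1 and T210A differed in their glucose responses at 1106 genes, 593 with a positive and 513 with a negative difference. The responses of SUC2 (2.96 ± 0.52, adjusted p = 0.0013), HXT2 (2.86 ± 0.43), INO1 (2.58 ± 0.33) and REG2 (3.004 ± 0.24) were higher in Alpha1, and those of BAP3 (-5.45 ± 0.41, with an Alpha1 mean close to the floor at low glucose) and SNO1 (-3.45 ± 0.26) lower. Of 33 proteasome genes 26 had a positive and 1 a negative difference, with the same counts when adjusted over the list alone (median 0.63, adjusted p = 3.43e-15), and this call held with an estimated correlation (adjusted p = 0.0042). Of 65 mitochondrial ribosome genes 34 had a positive difference (44 when adjusted over the list alone), with a median of 0.51 (adjusted p = 2.13e-13, and adjusted p = 0.666 with an estimated correlation). Of 21 genes for phospholipid synthesis under inositol control 11 had a positive and 1 a negative difference (11 and 2 when adjusted over the list alone), with a median of 0.59 (adjusted p = 9.78e-04, and adjusted p = 0.853 with an estimated correlation).

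**Figure D4:**
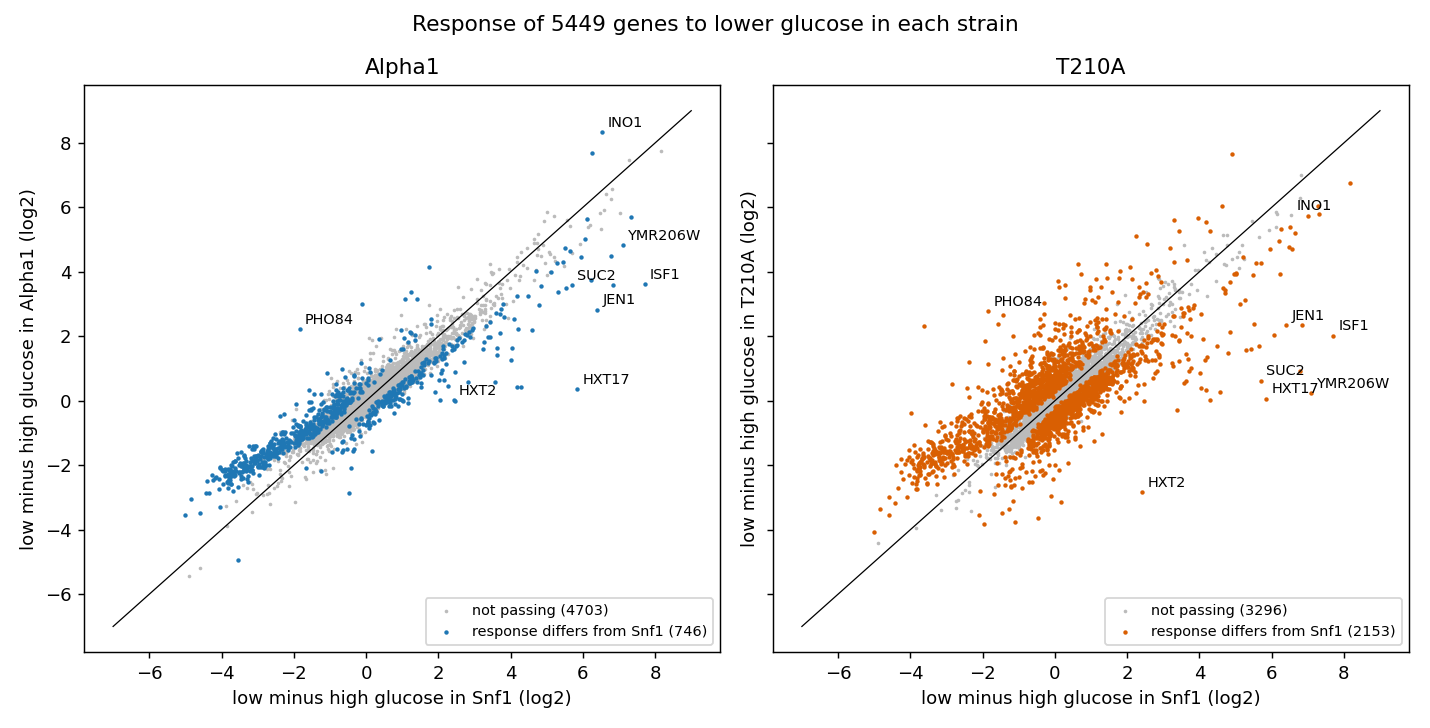
Log2 change from high to low glucose of 5449 genes in Alpha1 (left, vertical axis) and in T210A (right, vertical axis) against the change in Snf1 (horizontal axes), with the line of equal change. Coloured points mark the 746 and 2153 genes whose response differed from that in Snf1, and SUC2, JEN1 and HXT2 lie below the line in both panels.

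To ask where Alpha1 stood between Snf1 and T210A, the 3066 genes that separated T210A from Snf1 at low glucose were sorted by their calls in Alpha1. For 1235 of them (40.3%), HXK1 included, Alpha1 differed from T210A and not from Snf1. For 715 (23.3%), JEN1 included, it differed from Snf1 and not from T210A. Another 623 (20.3%), with SUC2, HXT2 and INO1 among them, differed from both, and 517 of these had Alpha1 between the other strains. INO1 was not one of the 517, with means of 11.95 in Alpha1, 10.40 in Snf1 and 9.07 in T210A. The remaining 493 (16.1%) differed from neither. The median share of the T210A difference seen in Alpha1 was 0.398. These classes count calls, and a gene that missed a call was not shown to be equal. The SNF1 signal, which may read plasmid transcripts, had low-glucose means of 12.94 in Alpha1, 8.57 in Snf1 and 9.31 in T210A. A difference in the amount of the plasmid-borne kinase and a difference in its catalytic domain therefore cannot be told apart in the Alpha1 contrasts. At high glucose 189 of 228 such genes (82.9%) differed from T210A alone, and of the 47 on other chromosomes, with calls from all genes, 18 did.

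Genes that differed from Snf1 in the same direction in Alpha1 and T210A numbered 1276 at low glucose, 753 higher and 523 lower, where independent calls would give 276 and 187, and 62 genes differed in opposite directions. BAP3 was not among the shared ones, and SUC2, HXT2, JEN1 and MRK1 were lower in both. The 2 sets of differences correlated at 0.72 across genes. In 100 simulations with unchanged strains set against the same 3 Snf1 arrays the correlation was 0.32. The covariance was 0.311 against a simulated 0.0081. No gene was shared in the simulations, but unchanged strains leave few calls to share, so that count sets no scale for the 1276. At high glucose 6 genes were shared, all lower, where independence would give 0.605 higher and 0.206 lower, and 1 had opposite directions. The shared number at high glucose was 0 to 4 with 1 array left out, and 0 in a fit and adjustment without chromosome VIII genes, although none of the 6 lies on that chromosome. There the correlation was 0.13 against a simulated 0.44, and the covariance 0.0061 against 0.0072. The 3 reference arrays entered both contrasts and are too few to divide, so part of any excess may come from them.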

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

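The tests of an extra chromosome copy, of single-gene regulation, of the pyrimidine pathway, of segments around SNF1, DET1 and URA3 at low glucose and of an earlier culture stage were chosen after the results had been seen, as was the omission of chromosome VIII genes.

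The strains differed in their responses to low glucose, by a test of the difference itself, at 746 genes for Alpha1 minus Snf1, 2153 for T210A minus Snf1 and 1106 for Alpha1 minus T210A. For Alpha1 minus Snf1 the largest positive values were PHO84 4.06, AAD6 3.11, YEL073C 2.40, CWP1 2.15 and ZRT1 2.07, and the largest negative ones HXT17 -5.50, ISF1 -4.09, RGI2 -3.85, YIG1 -3.74 and JEN1 -3.58. Those 5 genes and PHO84 had group means close to the floor, so the size of these differences is uncertain. PHO84 gave 4.86 without Alpha1_low replicate 1. ISF1 gave -3.50 without Alpha1_low replicate 2 and -4.76 without Alpha1_low replicate 3. HXT17 gave -3.61 with the mean of its probe sets. Among the anchor genes the values were SNF1 -0.81, SUC2 -2.11, ICL1 -1.51, HXT2 -2.41, INO1 1.80 and ACC1 0.44, and the ribosome biogenesis median was 1.29.

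T210A minus Snf1 gave BAP3 5.94, PHO84 4.62, EFM6 4.12, ATG41 3.96 and YOR302W 3.81 at the positive end, and YMR206W -6.87, MRK1 -5.86, HXT17 -5.78, ISF1 -5.69 and HXT2 -5.26 at the negative end, with means close to the floor for PHO84, YMR206W, MRK1, HXT17 and ISF1. With the mean of its probe sets HXT17 gave -3.75. Anchor genes gave SNF1 0.84, SUC2 -5.07, ICL1 -1.19, JEN1 -4.05 (with a mean close to the floor) and HXK1 -1.25, and the proteasome median was -0.65. Alpha1 minus T210A gave YMR206W 4.60, CWP1 3.75, MRK1 3.56, REG2 3.004 and SUC2 2.96, against BAP3 -5.45, BAG7 -3.88, SNO1 -3.45, SRL4 -3.24 and YNR068C -3.15, with means close to the floor for YMR206W, MRK1, BAP3, BAG7 and SRL4. MRK1 gave 2.94 without Alpha1_low replicate 3 and 4.23 with array weights. The anchor genes there gave SNF1 -1.65, HXK1 1.45, HXT2 2.86, INO1 2.58 and ACC1 0.49, and the proteasome median was 0.63.

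Probe sets without a gene name, which the main comparisons did not use, also held signals above the Snf1 reference. Of 218 such probe sets 1 was higher in Alpha1 and 5 in T210A at high glucose, and 21 and 62 were higher at low glucose. Lower signals were called for 5 and 1 at high glucose and for 29 and 52 at low glucose. Of the 5449 genes tested, in the same order, 17, 194, 927 and 1621 were higher and 33, 34, 705 and 1445 lower. Whether the unnamed probe sets differed from the genes in these shares was not tested.

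Chromosome VIII genes were higher in T210A at both glucose levels. Aberrant arrays are argued against, since the lowest chromosome VIII median among the 6 T210A arrays was 0.52 above the Snf1 mean. Separate regulation of single genes is also argued against, since 100% of the chromosome VIII genes with a mean of at least 8 had a positive difference at high glucose. An extra copy of the chromosome in the T210A cultures may account for the pattern: among genes of that signal at high glucose, the lowest median over 3 parts of the chromosome was 0.55, and no other chromosome had a median beyond 0.0623 in size. DNA was not measured, and whether such a copy arose by chance or under selection in this strain was not tested.

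SNF1, DET1 and URA3 signals were higher in Alpha1 than in Snf1. Amplified segments around the 3 genes are argued against at high glucose by a median difference over 18 neighbouring genes of -0.0302. No single neighbour there was above 0.22 (JIP4, near SNF1). At low glucose the median was 0.0354, but it was taken over the neighbours of all 3 genes at once. It could therefore miss a segment around 1 of them. Induction of the pyrimidine pathway is argued against for URA3 at high glucose by a median of -0.0304 over URA1, URA4 and URA10, and at low glucose, where that median was 0.77, it may add to the URA3 signal. At low glucose the means of URA10, URA1 and URA4 were 8.48 (SD 0.76), 8.33 and 7.94 in Alpha1. In Snf1 they were 7.71, 7.33 and 7.79. The rise was not particular to Alpha1, since T210A had means of 9.51, 8.06 and 7.66, and a URA3 mean of 10.95 against 10.05 in Snf1. The plasmid of the Alpha1 strain could be the source of the SNF1 and URA3 signals, but its sequence and copy number are not given, and this was not tested. No source of the DET1 signal other than an amplified segment was tested.

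Part of the response to lower glucose was missing in T210A and Alpha1. Scaling of the arrays is argued against for T210A, since quantile normalization gave 110% of the T210A minus Snf1 count and kept 1974 of its 2153 genes, while for Alpha1 minus Snf1 it kept 670 of 746 and moved the negative differences from 238 to 421. Alpha1 arrays at different stages of the course may add to the pattern in Alpha1, as replicate 3 deviated along the Snf1 response with a correlation of 0.64 across genes. An earlier stage of the T210A cultures cannot be told apart from a loss of kinase activity, which the design varies and which was not tested: of 320 genes that rose at least 4-fold in Snf1, 18 had a T210A response under 0.25 of that in Snf1 and a called difference, a number between the limits of 5 and 20 set for the 2 outcomes. Of the 320 genes 62.2% had at least 0.75 of the Snf1 response (median 0.82), which an equal lag of all genes could also give. Against an equal lag, HXT2 (2.42 in Snf1, -2.84 in T210A) and BAP3 (-3.61 and 2.33) moved in opposite directions in the 2 strains.

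Other assignments of the arrays to the groups were tried for each count. With 10 possible splits in each contrast of 2 groups the share cannot be under 0.05. Only 1 split, the real one, reached the count, and the highest other counts were 0 against 50, 0 against 228 and 1 against 344 at high glucose, and 3 against 1632, 0 against 3066 and 6 against 2263 at low glucose, each for Alpha1 and T210A against Snf1 and then Alpha1 against T210A. For low against high glucose they were 0 against 3669 in Snf1, 15 against 3461 in Alpha1 and 0 against 3841 in T210A. For the response differences 6, 8 and 4 of 100 splits gave at least 746, 2153 and 1106 genes, with highest other counts of 1178, 2355 and 1370. All of those splits kept the low-glucose arrays together by strain, and so kept part of the real difference between strains, and the highest counts with these arrays mixed were 23, 26 and 113. The shares therefore carry no verdict on chance.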

How the results depend on the processing

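Array weights and the omission of chromosome VIII genes were chosen after the data had been seen. No named gene or list result reversed its direction. Of the 47 genes with several probe sets, AAD4 had probe sets called in opposite directions for Alpha1 against T210A at low glucose. For T210A against Snf1 at low glucose 11 of the 47 were called by only part of their probe sets, the most of any comparison. Of 810 named gene results 808 kept their call with an intensity trend and robust prior, 711 in a fit of the compared groups alone (98 weaker, 1 stronger), 802 after quantile normalization, 801 after median centring, 810 with the mean of all probe sets and 790 with array weights (19 weaker, 1 stronger). Without the dimmest 25% of genes 633 of 636 kept it, above the 95th percentile of unnamed probe sets, which left 591 genes, 160 of 160, and without chromosome VIII 354 of 362. With 1 array left out 5807 of 6042 kept it. Of 172 called lists 4 kept their call with an estimated correlation, 133 with fry and 158 after quantile normalization. Signal over background limits what can be said of the genes described as close to the floor.

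The replicate number as a block kept all 810 named gene results and 166 of 172 list calls, and as a block within strain 499 of 504 and 108 of 110. It moved 1 count by more than 1.5 times, that of Alpha1 against T210A at high glucose, to 543 (200 higher, 343 lower). Same-numbered arrays of those groups deviated together with correlations of 0.17, 0.53 and -0.24, so not all 3 were above 0.1, and the labels do not say whether the numbers pair the arrays.

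Some counts moved by more than 1.5 times, and the cause was not tested except where fewer genes were counted by construction. For Alpha1 against Snf1 at high glucose, median centring gave 85. Array weights gave 396, 572 and 1241 at high glucose for Alpha1 against Snf1, T210A against Snf1 and Alpha1 against T210A, and 3252 for the T210A minus Snf1 response. A fit of the compared groups alone gave 603 for Alpha1 against Snf1 and 1244 for Alpha1 against T210A at low glucose, and 491 for the Alpha1 minus Snf1 response. The main fit pooled the variance of each gene over all groups. Alpha1 at low glucose had a root mean square gene SD of 0.336, against 0.133 to 0.186 in the other groups. Its array weights were 0.160, 0.194 and 0.523, against 0.338 to 5.80 elsewhere. The comparisons listed above for a fit of the compared groups alone all included Alpha1 at low glucose. That fit also has fewer residual degrees of freedom, so how far the spread itself moved the counts was not tested. Repeating the fit and adjustment without chromosome VIII genes gave 18 for T210A against Snf1 (7 higher, 11 lower, of 13 and 34 called on other chromosomes with all genes) and 80 for Alpha1 against T210A at high glucose (41 and 39 of 82 and 76). The shared genes, none of which lies there, then numbered 0. With the calls from all genes, 18 of the 47 genes on other chromosomes stood at the Snf1 side.

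A minimum of 2-fold left, by construction, 14, 34 and 59 genes at high glucose (Alpha1 against Snf1, T210A against Snf1, Alpha1 against T210A), 333, 900 and 394 at low glucose, 1655, 1292 and 1525 for low against high glucose in Snf1, Alpha1 and T210A, and 288, 814 and 298 for the responses of Alpha1 minus Snf1, T210A minus Snf1 and Alpha1 minus T210A. The 591 genes above the 95th percentile of unnamed probe sets (log2 9.80) gave, in the same order, 13, 33 and 40, then 197, 280 and 278, then 480, 460 and 510, then 76, 190 and 167. These counts are of 591 genes and not of 5449. At 2-fold the shared genes numbered 2 at high and 291 at low glucose. The classes at the Snf1 side, at the T210A side, against both and against neither held 29, 2, 0 and 3 genes at high and 254, 224, 394 and 28 at low glucose.

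The number of lists called with an estimated correlation was, in the same order, 0, 0 and 0 at high glucose, 0, 0 and 1 at low glucose, 0, 0 and 0 for low against high glucose, and 1, 1 and 1 for the responses, against 8, 3, 8, 19, 13, 11, 22, 23, 21, 19, 13 and 12 with the preset correlation. Fry gave 1, 0 and 1 at high glucose, 24 for T210A against Snf1 and 17 for Alpha1 against T210A at low glucose, 32 for low against high glucose in T210A, and 9 for the Alpha1 minus Snf1 response. The cause was not tested.

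With 1 array left out the counts ran, in the same order, from 19 to 39, 169 to 210 and 245 to 291 at high glucose, from 1301 to 1899, 2764 to 2819 and 1873 to 2401 at low glucose, from 3453 to 3520, 3183 to 3616 and 3574 to 3672 for low against high glucose, and from 587 to 1158, 1885 to 1977 and 908 to 1409 for the responses. Shared genes ran from 0 to 4 at high and from 1031 to 1428 at low glucose.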

Other observations

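Several gene groups beyond those already described differed at low glucose. Of 28 sulfur genes 14 were higher and 1 lower in Alpha1 than in Snf1 (15 and 1 when adjusted over the list alone), with a median of 0.34 (adjusted p = 5.29e-04, and adjusted p = 0.50 with an estimated correlation). Of 43 cell cycle genes 28 were lower in T210A than in Snf1, also when adjusted over the list alone (median -0.61, adjusted p = 1.88e-06, and adjusted p = 0.461 with an estimated correlation). Of 21 thiamine and vitamin genes 17 were higher and 1 lower in T210A (17 and 2 when adjusted over the list alone), with a median of 0.86 (adjusted p = 0.0010, and adjusted p = 0.629 with an estimated correlation). Of 24 purine genes 16 were lower and 3 higher in T210A (16 and 5 when adjusted over the list alone), among them ADE17 (6.42-fold lower), with a median of -0.71 (adjusted p = 0.0307, and adjusted p = 0.859 with an estimated correlation).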
